A study of Mus musculus with 4 samples.

How the data were processed

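RNA of the mouse left hemi-diaphragm was measured on 4 one-colour oligonucleotide arrays, 2 of the synaptic region and 2 of the non-synaptic region. The deposited values are intensities on a linear scale, 1 per probe set, for 45101 probe sets including 64 control probe sets. The scanner, the summary method and the scaling are not given in the sources used here. The 2% trimmed mean of the deposited intensities was 2500 on each of the 4 arrays, so the arrays had been brought to a common level and this scaling was kept. Such a scaling sets each array's average level to the same value, so a change shared by most transcripts would not be seen.

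Intensities below a floor of 158.891, the 20th percentile of all values, were raised to it and log2 was taken, so that the lowest possible log2 value was 7.31. A difference against a region with both arrays at the floor is a lower bound on its size, given as "at least". Probe sets with a mean log2 value below 8.87, the 40th percentile, were left out, as were the control probe sets. This left 26480 probe sets. Signal near the floor limits what can be measured of weakly expressed transcripts, and the number of arrays limits the precision.

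Gene names came from the array's platform annotation, which can be old. Of all probe sets, 34958 had 1 gene, 932 had several and 9211 had none. Symbols were updated through the Entrez identifier with RefSeq gene tables of assembly GRCm38.p6, which matched 34754 probe sets and left 204 with the annotation's own symbol. That assembly was used only for names and for which genes are neighbours. Each gene was read from the probe set with the highest mean log2 value among those annotated to it alone, giving 12363 genes. The other probe sets of a gene are cited where they differ.

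The regions were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior worth 3.16. Standard errors are those of the moderated fit. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so none was used. The sample titles end in e1_le1 or e1_le2, without explanation. The number after le is called the replicate number here, which is a reading of the titles and not stated by them. Nothing in the labels says that the arrays of a region came from separate animals, so p-values measure only the spread between arrays, which may be technical.

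The design, the alternatives, the rule for naming genes and 27 gene lists were set before the data were examined. The lists cover parts of the neuromuscular synapse, muscle fibre types, metabolism, stress responses and markers of other cell types that a piece of diaphragm could hold. Lists with at least 3 measured members were tested with camera, limma's competitive gene set test, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 25 lists. Each list was also tested with the correlation estimated from the data and with fry. Member counts are given adjusted over all probe sets and adjusted over the list alone. Another 5 lists were added afterwards and adjusted among themselves.

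The genes named are all members of the lists of acetylcholine receptor subunits, postsynaptic organisers and scaffold, synaptic basal lamina, and denervation and inactivity genes. To these were added the 12 genes with the largest difference in each direction among those past the threshold with both arrays of a region on the same side of both others, filled up by smallest unadjusted p where fewer passed. Of each other list, up to 4 members with the smallest unadjusted p and up to 2 with the highest mean were added. Genes outside this rule are said to have been chosen after their values were seen.

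Alternatives were quantile normalization, median centring, other filters and floors, other variance priors, an unmoderated test, other thresholds, the replicate number as a block, leaving out each array in turn and, for the lists, the mean of all probe sets of a gene. The scheme was tested on simulated data made from 26480 probe sets with 50 changed at each of several sizes.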

Results

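The diaphragm is the main muscle of breathing, and its motor nerve contacts the fibres in a narrow band across the muscle. Transcript levels were measured in the left hemi-diaphragm of the mouse, in the synaptic region and in the non-synaptic region, on 2 arrays each. The median intensity of the 2 synaptic arrays was 658 and 769, and that of the 2 non-synaptic arrays was 704 and 738. Between 18.7% and 21.3% of probe sets per array lay at the floor. The ratio of 3' to 5' signal of Gapdh, a sign of RNA quality, was 1.03 and 0.814 in the synaptic arrays and 0.853 and 0.815 in the non-synaptic arrays. The median absolute log2 difference between the 2 synaptic arrays was 0.351 and between the 2 non-synaptic arrays 0.298. Between arrays of different regions with the same replicate number it was 0.204 and 0.158. No probe set had exactly the same deposited intensity on any pair of arrays.

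The comparison asks which transcripts differ in level between muscle that holds the synapses and muscle that does not. Mbp, which encodes myelin basic protein, rose in the synaptic region by 3.50 ± 0.17 on the log2 scale (SE, n = 2 arrays per region, limma adjusted p = 0.0326), from an intensity of 3768 ± 244 to 42719 ± 2268 (SD). Adipoq, which encodes the fat cell hormone adiponectin, fell (adjusted p = 0.0326). Its synaptic arrays, at log2 values of 7.54 and 7.56, lay just above the floor of 7.31, so only a bound on the size is given: at least 17.3-fold lower with the floor raised to the 40th percentile, a setting in which the call was lost (adjusted p = 0.284). The call of Mbp was lost with the raised floor as well (limma adjusted p = 0.138), and both calls were lost with no filter or no intensity trend. In the lists of the synapse, Ache, Chrna1, Chrne, Etv5 and Cd24a had log2 differences from 1.97 to 3.11. They passed when adjusted over their lists alone and not over all probe sets. Both synaptic arrays lay above both non-synaptic arrays for each of these 5 genes. Nes at 1.06 and Prkar1a at 1.02 passed over their list alone too, while most members did not. Those passing were 2 of 3 acetylcholine receptor, 4 of 25 postsynaptic and 1 of 17 basal lamina genes. The postsynaptic and basal lamina lists had medians of 0.10 and 0.05. Markers of Schwann cells were higher in the same arrays, with a median of 1.10.

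Of the 5 acetylcholine receptor subunits, 3 were measured above the filter. Chrna1, the alpha subunit of the muscle receptor, was higher by 1.97 ± 0.19 (adjusted p = 0.000381 over the list alone, 0.198 over all probe sets). Chrne, the subunit of the adult receptor, was higher by 3.11 ± 0.67 (adjusted p = 0.00757 over the list alone), with a spread of 1.28 (SD) between its 2 non-synaptic arrays. The difference of Chrne was 4.01 without replicate 1 and 2.20 without replicate 2 of the non-synaptic region, and it passed over the list alone in both. Chrnb1 differed by 0.03 ± 0.23. Adjusted over the list alone, 2 of the 3 rose, and 0 of the 3 passed over all probe sets by limma, with 2 at an unadjusted p under 0.05. Chrnd and Chrng lay below the filter. The list, with a median of 1.97, stood above other genes with camera (adjusted p = 1.90e-07), which was lost with an estimated correlation (adjusted p = 0.250 with an estimated correlation), while fry, which tests whether the genes move one way and not whether they differ from other genes, gave an adjusted p of 0.0124.

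**Figure D1:**
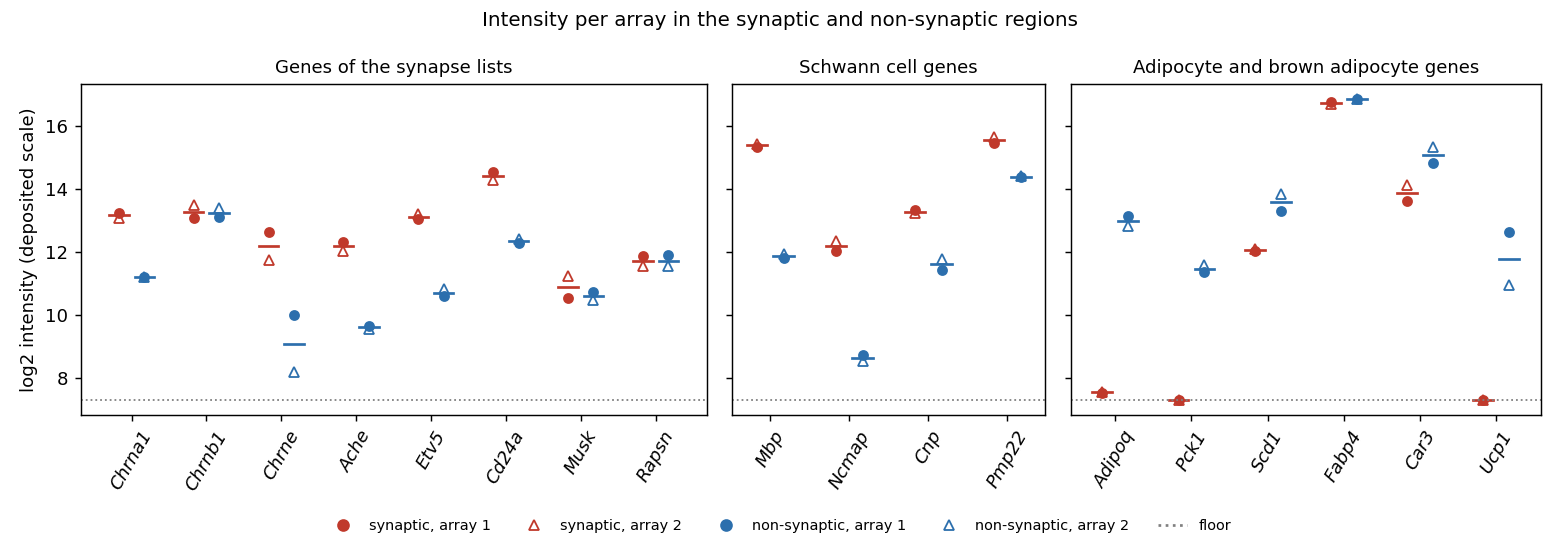
Log2 intensity of single genes on each array (vertical axis), in red for the synaptic and blue for the non-synaptic region, with filled circles for replicate 1, open triangles for replicate 2, bars for the means of the 2 arrays and a dotted line at the floor of 7.31. Mbp lies at a mean of 15.38 in the synaptic and 11.88 in the non-synaptic region, Adipoq at 7.55 and 12.98, and Chrnb1 at 13.27 and 13.24.

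Of the 31 genes of the postsynaptic organisers and scaffold, 25 were measured, and 4 rose adjusted over the list alone against 0 over all probe sets by limma, with 5 at an unadjusted p under 0.05. Etv5, an ETS transcription factor, was higher by 2.41 ± 0.21 (adjusted p = 0.000990 over the list alone), and its 3 probe sets gave from 1.43 to 2.41. Cd24a, a cell surface glycoprotein, was higher by 2.06 ± 0.18 (adjusted p = 0.000990 over the list alone), with 1.80 to 2.06 over its 3 probe sets. Cd24a is known from published work on the neuromuscular synapse that may include these arrays, so its place in the list is not independent evidence. Nes, which encodes the intermediate filament nestin, was higher by 1.06 ± 0.18, and Prkar1a, a regulatory subunit of protein kinase A, by 1.02 ± 0.24. The other probe set of Nes gave 0.30, and the others of Prkar1a gave 1.44 and 0.12. Cd24a and Nes are also known from cells other than muscle fibres, and Erbb3, also known from Schwann cells, differed by 0.63 ± 0.23 and did not pass. The receptor tyrosine kinase Musk differed by 0.28 ± 0.32, its activator Dok7 by -0.54 ± 0.37, the agrin receptor Lrp4 by 0.32 ± 0.21 and the receptor-clustering protein Rapsn by 0.005 ± 0.24, none of them past the test. The synaptic arrays of Dok7 were at 13.09 and 12.05, against a non-synaptic mean of 13.12, and its second probe set gave 0.12. The list had a median of 0.10, and its camera call (adjusted p = 7.40e-06) was lost with an estimated correlation (adjusted p = 0.425 with an estimated correlation). Without replicate 1 or without replicate 2 of the non-synaptic region, 2 of the members passed over the list alone in place of 4, with Nes at an adjusted p of 0.201 and 0.0977 and Prkar1a at 0.351 and 0.0977. Nes did not pass without replicate 1 of the synaptic region either (0.0660), nor Prkar1a without its replicate 2 (0.0621).

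Of the 19 genes of the synaptic basal lamina, 17 were measured and 1 rose adjusted over the list alone. This was Ache, which encodes the acetylcholinesterase that ends transmission, higher by 2.58 ± 0.23 (adjusted p = 0.00148 over the list alone, 0.165 over all probe sets). Agrin, encoded by Agrn, differed by 0.04 ± 0.31 and the laminin chain Lamb2 by 0.05 ± 0.20. The list had a median of 0.05 and a camera adjusted p of 0.0132, with an adjusted p = 0.425 with an estimated correlation. Of 12 measured genes known to respond to denervation or inactivity, 1 rose adjusted over the list alone, and this was again Chrna1. In that list the myogenic factor Myog differed by -0.12 ± 0.27 and Gadd45a by 0.12 ± 0.20, and the list, with a median of 0.06, did not pass camera (adjusted p = 0.122).

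Markers of Schwann cells, the glia that wrap motor axons, were the list with the largest number of raised genes. Of 22 members 15 were measured, and 8 rose adjusted over the list alone, against 1 over all probe sets. All 15 had a positive difference, 14 of them with both synaptic arrays above both others, and the median was 1.10. Beside Mbp, these included Ncmap at 3.54 ± 0.26, Cnp at 1.68 ± 0.21 and Pmp22 at 1.16 ± 0.15, all known from myelin, and the transcription factor Egr2 at 1.37 ± 0.41. The 8 probe sets of Mbp differed in size, from 0.23 to 3.82. The camera adjusted p was 2.06e-34, and the call was lost with an estimated correlation (adjusted p = 0.115 with an estimated correlation). The estimate was -0.046, below the preset 0.01, so correlation between the members does not account for that loss. The adjusted p of fry was 0.0124. Egr2 did not pass over the list alone without replicate 1 of the non-synaptic region (adjusted p = 0.164) or replicate 2 of the synaptic region (0.0826), and without replicate 1 of the synaptic region it lay below the filter. Of 18 markers of axons and neurons, whose cell bodies lie outside the muscle, 4 were measured and 0 passed the limma test over the list alone or over all probe sets, with a median of -0.02, a mean of 0.05 and a test direction below 0. None of these 4 had an unadjusted limma p under 0.05. The 4 measured markers of the perineurium, the sheath of nerve bundles, had a median of 0.28 (adjusted p = 0.0669).

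Fat cell markers were lower in the synaptic region. Of 11 adipocyte genes 7 were measured, and 5 fell adjusted over the list alone, against 1 over all probe sets. Adipoq had an intensity of 8144 ± 1275 in the non-synaptic region. Pck1, an enzyme of glyceroneogenesis and gluconeogenesis, was at the floor on both synaptic arrays and so was at least 17.9-fold lower there, with a log2 difference of -1.35 on its second probe set. Scd1, a fatty acid desaturase, differed by -1.50 ± 0.24 and Car3, a carbonic anhydrase, by -1.19 ± 0.27. Scd1 and Car3 kept intensities of 4318 ± 144 and 15314 ± 3807 (SD) in the synaptic region, where Adipoq was just above the floor. They may thus not mark fat cells alone. Fabp4, a fatty acid binding protein of fat and endothelial cells, differed by -0.12 ± 0.13 and did not pass. The list's median was -1.50 and its camera adjusted p 1.14e-22, with an adjusted p = 0.115 with an estimated correlation and an adjusted p of 0.00437 with fry. Without replicate 2 of the non-synaptic region, 3 members passed over the list alone in place of 5, with Car3 at an adjusted p of 0.0617 and Pck1 below the filter. Pck1 lay below the filter without replicate 1 of that region as well. Of the 6 brown adipocyte genes 1 fell adjusted over the list alone. This was Ucp1, the uncoupling protein of brown fat, at the floor on both synaptic arrays and at least 22.3-fold lower there. Its log2 values were 12.63 and 10.96 on the 2 non-synaptic arrays, so that the bound was 12.5-fold without replicate 1, where Ucp1 lay below the filter and was not tested, and 39.8-fold without replicate 2. Ucp1 did not pass over the list alone when no filter was set. Cidea differed by -0.75 ± 0.30. The brown adipocyte list had a median of -0.26 and passed camera (adjusted p = 0.00167) but not with an estimated correlation (adjusted p = 0.417 with an estimated correlation).

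**Figure D2:**
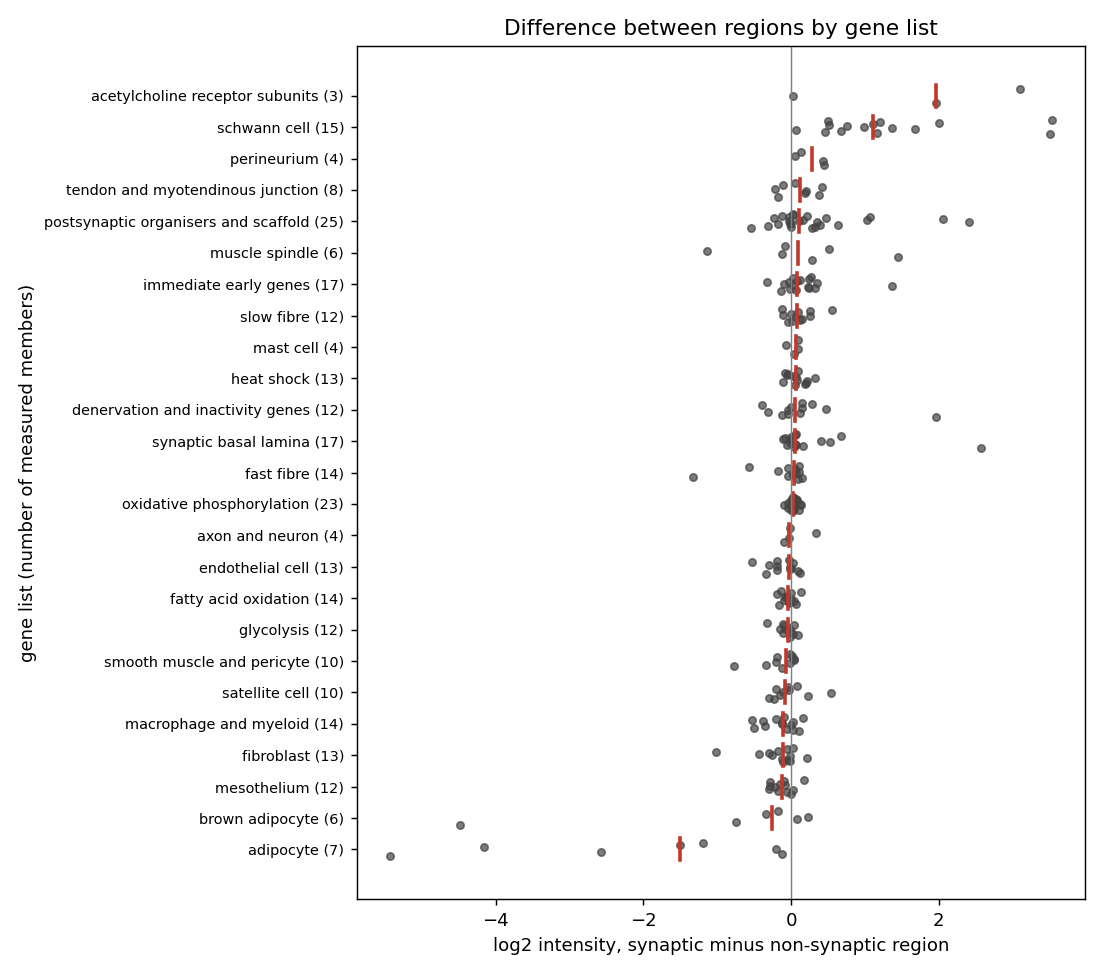
Log2 difference of synaptic minus non-synaptic region (horizontal axis) for each measured member of 25 gene lists, 1 dot per gene, with a red line at each list's median. The Schwann cell list has a median of 1.10 and the adipocyte list of -1.50, while the medians of the fibre type and metabolic lists lie between -0.04 and 0.08.

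Of 14 fast fibre genes 1 fell adjusted over the list alone. This was Myh4, the myosin heavy chain of the fastest fibres, at -1.32 ± 0.18, and at -1.60 on its second probe set. The call of Myh4 was lost without replicate 1 (adjusted p = 0.0794) and without replicate 2 (0.113) of the non-synaptic region, and when no filter was set. Mybpc2, a fast myosin-binding protein, differed by -0.58 ± 0.19 and the fast fibre actinin Actn3 by -0.18 ± 0.14, both with the regions apart and neither past the test, and the fast myosin Myh2 differed by 0.15 ± 0.17. The fast fibre list had a median of 0.04, a mean of -0.11 and a test direction below 0 (adjusted p = 0.249). The 12 slow fibre genes had a median of 0.08 (adjusted p = 0.158), and Myh7, the slow myosin, differed by -0.05. Of 6 measured genes of the muscle spindle, 1 rose adjusted over the list alone, the embryonic myosin Myh3 at 1.45 ± 0.28, and the list, with a median of 0.10, did not pass (adjusted p = 0.122). Myh3 was not past the test without replicate 1 of the non-synaptic region (adjusted p = 0.134) or replicate 2 of the synaptic region (0.0817), nor when no filter was set.

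Metabolic and stress genes did not pass in any list. The medians were -0.04 for glycolysis (adjusted p = 0.211), 0.03 for oxidative phosphorylation (0.458), -0.04 for fatty acid oxidation (0.254), 0.08 for immediate early genes (0.128) and 0.06 for heat shock genes (0.294). By limma, 0 of the 79 measured members of these 5 lists passed when adjusted over the list alone, and at an unadjusted p under 0.05 the counts were 1 higher and 0 lower. The higher member was Egr2, which the Schwann cell list also holds.

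Markers of the other cell types of a muscle piece were near 0 or slightly below. Medians were -0.03 for endothelial cells (adjusted p = 0.122), -0.07 for smooth muscle and pericytes (0.0324), -0.12 for fibroblasts (0.0374), -0.11 for macrophages and myeloid cells (0.0422) and -0.12 for mesothelium (0.0994). Medians of tendon (0.12, adjusted p = 0.459), mast cells (0.07, 0.699) and satellite cells (-0.08, 0.681) did not pass. By limma, 0 of the 84 measured members of these 8 lists passed adjusted over the list alone, and at an unadjusted p under 0.05 the counts were 0 higher and 2 lower. The camera calls of smooth muscle, fibroblasts and myeloid cells were lost with an estimated correlation, with adjusted p = 0.425, 0.675 and 0.648 with an estimated correlation. The direction of the fibroblast list reversed without replicate 1 of the synaptic region and without replicate 2 of the non-synaptic region. The median was 0.56 for 2 lymphocyte genes and -0.05 for 2 red blood cell genes, which were too few to test. Without replicate 1 of the synaptic region the lymphocyte median was -0.25, and without replicate 2 it was 1.37. The red blood cell median was 0.13 without replicate 2 of the synaptic region and -0.23 without its replicate 1.

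Over all 26480 probe sets, limma called 1 higher and 2 lower at an adjusted p under 0.05. These were Mbp, Adipoq and a probe set to which the annotation used here gives no gene, which was chosen for mention after its values were seen (adjusted p = 0.0280). Its synaptic arrays also lay just above the floor, and it was at least 30.5-fold lower there with the floor raised to the 40th percentile (adjusted p = 0.138). At an unadjusted p under 0.05 the counts were 173 higher and 88 lower, where chance would give 1324 in all. Both synaptic arrays lay above both others for 9.89% of probe sets and below both for 9.98%, against 16.7% by chance in each direction. These chance values assume arrays that vary independently, whereas arrays with the same replicate number lay closer to each other than arrays of the same region did. Among the genes set apart in this way, 75 were at least 2-fold higher and 37 at least 2-fold lower. The remaining higher genes with the smallest unadjusted p were Kcne1l, a potassium channel subunit, at 3.69 ± 0.26, the calcium-binding protein Cabp7 at 3.85 ± 0.39, Ufsp1 at 2.18 ± 0.24, Crym at 1.90 ± 0.24 and Ugt8a, an enzyme of myelin lipid synthesis, at 3.21 ± 0.41, none past the threshold over all probe sets. For Cabp7 and Ugt8a 1 of the 2 non-synaptic arrays was at the floor and the other at 8.17 and 7.51, so the sizes given are lower bounds. The remaining lower genes with the smallest unadjusted p were the cysteine dioxygenase Cdo1 at -2.05 ± 0.27, Cytl1 at -2.02 ± 0.28, haptoglobin (Hp) at -2.80 ± 0.40, Cyp2e1 at -1.88 ± 0.30, Rab11fip4 at -1.88 ± 0.37 and Pi16 at -1.02 ± 0.22, also not past it. For Hp 1 of the 2 synaptic arrays was at the floor and the other at 7.96, so its size is a lower bound too. Centring each array on its median gave 6 higher and 2 lower. Without replicate 1 of the non-synaptic region no probe set passed (adjusted p of Mbp 0.336), and likewise without its replicate 2 (0.149).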

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

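The list counts, bounds and medians without each array, the bounds with a raised floor and the list counts with the block were tests chosen after seeing the data. The rest was planned. Quantile normalization, no floor, a robust prior and a minimum log2 change of 1 left the counts at 1 probe set higher and 2 lower. The higher count became 6 with median centring, 0 without a filter, 3 with the filter at the 60th percentile, 0 with the floor at the 40th percentile, 0 without an intensity trend, 6 at an adjusted p under 0.10 and 0 with an unmoderated test. The lower count became 0 without a filter, with the floor at the 40th percentile, without a trend and with the unmoderated test, and 3 at an adjusted p under 0.10. Leaving out each array gave from 0 to 6 higher and from 0 to 5 lower: 0 in all without either non-synaptic array, 4 and 3 without replicate 1 of the synaptic region, and 6 and 5 without its replicate 2. The cause was not tested. Of the 180 named genes, 27 passed the threshold in some setting, and 0 of these changed sign where they were measured. Of the others, 85 changed sign in some setting. Adjusted over the list alone and without a filter, 1 acetylcholine receptor, 5 Schwann cell, 3 adipocyte and 0 brown adipocyte, fast fibre and muscle spindle genes passed, so the calls of Ucp1, Myh4 and Myh3 were lost. With the filter at the 60th percentile, 3 adipocyte genes passed and the brown adipocyte and muscle spindle lists had 0.

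The number of lists past camera, 9, became 4 without a filter and 0 with an estimated correlation. In fry, which tests movement in 1 direction and not a difference from other genes, 3 passed. Adjusted p with an estimated correlation were 0.250 (acetylcholine receptor), 0.425 (postsynaptic, basal lamina, smooth muscle), 0.115 (Schwann cell, adipocyte), 0.675 (fibroblast), 0.648 (myeloid) and 0.417 (brown adipocyte). The adjusted p of fry were 0.145 (postsynaptic), 0.505 (basal lamina, brown adipocyte), 0.419 (smooth muscle), 0.787 (fibroblast) and 0.735 (myeloid). Without a filter those of camera were 0.1003 (basal lamina), 0.0507 (smooth muscle), 0.134 (fibroblast), 0.108 (myeloid) and 0.0968 (brown adipocyte). The filter at the 60th percentile gave 0.0572 for basal lamina and 0.0291 for denervation. Smooth muscle had 0.0550 with median centring. Without a trend, smooth muscle, fibroblast and myeloid had 0.0652, and with the floor at the 40th percentile fibroblast and myeloid had 0.0599. Fibroblast had 0.107 with the mean of all probe sets. Leaving out each array gave from 1.98e-05 to 0.724 for basal lamina, 0.0585 to 0.576 for smooth muscle, 1.07e-05 to 0.576 for fibroblast, 0.00493 to 0.999 for myeloid and 1.04e-07 to 0.159 for brown adipocyte. The fibroblast direction reversed without replicate 1 of the synaptic region (0.259) and without replicate 2 of the non-synaptic region (0.576). Of the 16 lists not past the threshold, 9 passed without some array, glycolysis (0.0163) and fatty acid oxidation (0.0120) with quantile normalization, and perineurium (0.00800) and muscle spindle (0.0197) with the floor at the 40th percentile. Perineurium also passed with the mean of all probe sets (0.0356).

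With the replicate block, 56 probe sets were higher and 18 lower, 1661 had an unadjusted p under 0.05 against 261 without it, and the denervation list had an adjusted p of 0.0257 and the endothelial list of 0.0144. The block brought 25 of the 180 named genes past the threshold over all probe sets, among them Etv5 (adjusted p = 2.65e-05), Cd24a (4.24e-05), Chrna1 (7.42e-05), Ache (0.000126) and Chrne (0.000320). Deviations of same-numbered arrays correlated at 0.634 across probe sets, and the first principal component, 68.6% of the variance, separated the numbers. The labels do not say what the number marks and there are only 2 pairs, so it was not taken as a pairing. Splitting the arrays by number called 4287 probe sets against 3 for the regions, which points to a structure of the samples. In data simulated with such a number effect, the fit without the block recovered 8% of changes of 2 on the log2 scale and 64% of changes of 4 with 0 false calls, and the block recovered 100% of both with 48 false calls. The block also recovered 34% of changes of 0.5 and 68% of changes of 1, where the fit without it recovered 0% of each. A gene that did not pass over all probe sets may therefore still differ by 1 on the log2 scale. The false calls of the block were a larger share than the threshold of 0.05 allows, so adjusted p with the block may be too small. Without such an effect, the fit without the block recovered 96% and 100% with 13 false calls, and the block 96% and 100% with 27.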

Other observations

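The lists of ion channels, cholesterol synthesis, unfolded protein response and further Schwann cell and adipocyte genes were added after the data were seen. Of the tests of explanations, that of muscle fibre share, that of non-muscle tissue of every kind and that of the Ufsp1 probe set were chosen only after the results were seen.

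Among 14 measured potassium and sodium channel genes, 3 rose adjusted over the list alone and 0 over all probe sets, namely Kcne1l at 3.69 ± 0.26, Kcna1 at 2.08 ± 0.28 and the sodium channel beta subunit Scn3b at 1.44 ± 0.20. Their values had been seen before the list was made, so its camera adjusted p of 2.51e-09 (adjusted p = 0.0756 with an estimated correlation) is not independent evidence. Kcna1 encodes a potassium channel known from myelinated axons, and Kcna2, often found with it, was at 1.26 ± 0.36 and did not pass. The 11 measured genes of cholesterol synthesis had a median of 0.06 (adjusted p = 0.290), and the 13 genes of the unfolded protein response had a median of -0.04 (adjusted p = 0.585). Members of the fixed lists outside the naming rule, chosen after their values were seen, were the Schwann cell genes Pllp at 1.997 ± 0.45, Fa2h at 1.21 ± 0.27 and Foxd3 at 1.10 ± 0.35, and the fat cell hormone Retn at -2.57 ± 0.61, all past the test over the list alone. Without replicate 1 of the synaptic region Retn was at -1.69, and without its replicate 2 at -3.45. Foxd3 did not pass without replicate 1 of either region (adjusted p = 0.157 and 0.0775) or replicate 2 of the non-synaptic region (0.164), nor Fa2h without replicate 1 of the synaptic (0.0573) or replicate 2 of the non-synaptic region (0.0790). Etv4, an ETS factor related to Etv5, lay below the filter, with a mean of 10.25 in the synaptic region and at the floor in the other. It did not pass over all probe sets when no filter was set.

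Schwann cell markers were higher in the synaptic region. A smaller share of muscle fibre RNA in that piece would raise markers of every other cell type, but the highest median of the endothelial, fibroblast and myeloid lists was -0.029, with an upper 95% bootstrap bound over these lists of 0.025, against 0.55 for 50% of the Schwann cell median. The bound is taken over genes and leaves out the spread between arrays, so it is too narrow. The fibroblast direction reversed without replicate 1 of the synaptic region and without replicate 2 of the non-synaptic region. A larger share of peripheral nerve is a candidate explanation that stays open. A second list of 11 measured Schwann cell genes, none used to find the pattern, had a median of 0.38 (interval 0.12 to 0.67, camera adjusted p = 1.12e-07). This median lay below the 1.10 of the first list and below 0.55, though its interval reached past 0.55. Higher levels per Schwann cell would raise the second list too, so it cannot tell these explanations apart. The call of that list was lost with an estimated correlation (adjusted p = 0.0756). Higher levels per Schwann cell near the synapse were not tested and stay open.

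Adipocyte markers were lower in the synaptic region. More non-muscle tissue of every kind in the non-synaptic piece is argued against by the endothelial, fibroblast and myeloid lists, the lowest median of which was -0.12 (-0.115), with a lower bound of -0.28 against -0.75. That bound too is taken over genes and leaves out the spread between arrays. Adipose tissue carried with the non-synaptic piece is a candidate explanation that stays open: a second list of 14 measured adipocyte genes had a median of -0.027 (interval -0.355 to 0.039), though its camera adjusted p was 0.0105 (adjusted p = 0.352 with an estimated correlation). The rule written beforehand asked for a median under -0.3 and a camera p under 0.05, and took a median over -0.1 as going against the explanation. The median fell on the side against. Its interval, which was not part of that rule, reaches past both limits, and the members went both ways, so the explanation is kept open.

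Ache and Ufsp1, which is the next protein-coding gene to it in GRCm38.p6 and does not overlap it, were both higher in the synaptic region. A change shared by all genes near Ache is argued against by the 5 measured neighbours Trim56, Srrt, Trip6, Slc12a9 and Ephb4, which had a median of 0.028 (interval -0.026 to 0.065). That interval is taken over the genes and leaves out the spread between arrays. The SE of single neighbours ran from 0.20 to 0.27, small beside the difference of 2.58 for Ache. On the side of Trim56, the genes between it and Ache (Muc3, Gm31160, Gm40349 and Muc3a) gave no value, so they are not covered. A Ufsp1 probe set that reads transcripts running on from Ache could give the same picture and cannot be told apart from a change of Ufsp1 itself. The difference of Ufsp1 minus Ache was -0.40 with an SE of 0.336. This SE treats the 2 genes as independent although they were read on the same arrays, so it cannot decide. The second probe set of Ufsp1 gave 0.86 against 2.18 for the first. The condition written for such a reading, the same difference on both probe sets, was not met. A regulation of both genes by the synapse was not tested and stays open.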
